A study of Mus musculus with 6 samples.

How the data were processed

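RNA was measured in 6 libraries of 4T-1 cells, a mouse mammary carcinoma line, 3 from wild-type cells and 3 from Lyplal1 knockout cells, all untreated. Per the labels' protocols, total RNA was taken with Trizol and made into DNBseq RNA-seq quantification libraries. The submitters' processing notes name STAR 2.7.8a, featureCounts 2.0.1 and the mouse build GRCm38, with no roles, order or settings. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here.

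The authors deposited whole-number counts per gene and TPM for 55487 genes in every library. Each library also has its own count and TPM file, and all 12 of these held the same values as the matching columns of the tables of the whole series, so only the whole-series tables were used. The deposited TPM were each gene's count divided by a gene length common to all libraries and scaled to a common total, as tried on 8077 genes, so they hold no reads beyond the counts. No row of the tables lacked a gene. Gene identifiers were matched to GENCODE release M21, which is on GRCm38, and 55227 of them had an entry there. Symbols, positions, exon lengths and GC content come from that release. The symbol of the gene now called Sting1 is Tmem173 in it.

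Total counts per library ran from 16731209 to 17108975, and 27543 genes had at least 1 count in some library. Genes with low counts were removed with the default filter of edgeR (filterByExpr), which left 13022 genes. The main comparison was edgeR's quasi-likelihood F test with robust estimates and TMM factors, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Standard errors of log2 fold changes were derived from the fitted change and its F statistic. CPM values are counts scaled to the TMM-adjusted library size. Fold changes and log2 fold changes are knockout over wild type unless the sentence says otherwise.

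Gene lists were tested with camera from limma on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 28 lists that had at least 5 tested members. Of 32 lists fixed before the data were examined, the other 4 are described by their members. Camera with a correlation estimated for each list and fry were run beside it. Counts of list members that rose or fell come from edgeR, once adjusted over all tested genes and once adjusted over the list alone. Another 11 lists were written after the data had been seen and are used only where that is said.

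The genes named in the text follow a rule fixed before the data were examined. It takes 22 genes chosen for the question. It takes the 12 largest rises and the 12 largest falls by fitted log2 fold change among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups. It takes up to 4 called members with the smallest adjusted p from each described list, or up to 2 with the largest change where none was called. It also takes the 3 called genes with the smallest adjusted p in each direction. Gene models with only a provisional name were passed over in the ranking, which removed 1 gene among the rises. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

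For a gene with no count in any library of a group, the fold is a lower bound against a floor of 3 counts over that group. For a gene with 1 to 3 counts in a group, the fold is the ratio of pooled counts, scaled by library size, with an exact 95% interval. Such intervals and floors cover counting error only. Some named genes share exon positions with another gene, among them Irf3, Cxcl10, Irf7, Cd274, Car9, Tap1, Tapbp, Mboat2, Eomes, Ankrd37 and Cldn3, and with the counting settings unknown their values are less certain.

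The test was tried on simulated counts for all 13022 genes, drawn from the means, library sizes and dispersions of these libraries with 200 genes changed. It recovered 80% of the genes changed 1.5-fold and 92% of those changed 2-fold, with 14 calls among unchanged genes. Camera called the shifted list and 0 of 20 unshifted lists. Simulated genes were drawn independently and few were changed, whereas 82.3% of tested genes were called in the data. The simulation therefore does not test the scaling, or lists of correlated genes, under such wide change.

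Alternatives comprised RLE and upper-quartile factors, DESeq2, limma-voom, no filter, a stricter filter of 1 CPM in 3 libraries, a test against a 1.2-fold change, the replicate number as a block, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library. Removing genes at least 2-fold higher in knockout replicate 3 than in the mean of the other knockout libraries was added after seeing the data. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and SciPy 1.17.1.

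The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. All 3 knockout libraries carry the same code in their descriptions, so a second, independently made knockout population was not analysed here.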

Results

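Gene expression was profiled by RNA sequencing in 4T-1 cells, a mouse mammary carcinoma line, that were wild type (n = 3) or knocked out for Lyplal1 (n = 3). Lyplal1 encodes a lysophospholipase-like protein of the family of acyl-protein thioesterases. The series title ties it to removal of palmitate from cGAS, the cytosolic DNA sensor that signals through STING to interferon genes, and to the response to immunotherapy. The comparison therefore asks which transcripts differ between cells labelled wild type and Lyplal1 knockout, with interest in the interferon branch. Total counts were 17108975, 17048072 and 17007616 in the wild-type libraries and 16731209, 16770387 and 16784906 in the knockout libraries. The groups stood apart along the leading principal component, which held 95.1% of the variance. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.994 to 0.997 within groups and 0.878 to 0.884 between groups. Chi-square values per gene between libraries of the same group were 1.44 to 3.81, above sampling noise, so no library is a copy of another, though this spread may be technical and the highest values, 3.55 and 3.81, involve knockout replicate 3.

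The Lyplal1 transcript (ENSMUSG00000039246, chromosome 1, 186087731 to 186117310, GRCm38) was still present in the knockout libraries. It had 76, 73 and 68 counts in wild-type replicates 1 to 3 and 54, 48 and 58 counts in knockout replicates 1 to 3. Mean levels were 4.05 ± 0.212 CPM in wild type and 3.34 ± 0.328 CPM in knockout (SD, n = 3 each). Its log2 fold change was -0.28 ± 0.15 (SE), which missed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0886). With upper-quartile factors it was called lower at a log2 fold change of -0.41 (adjusted p = 0.014), and on log2(TPM + 1) at -0.44 (limma-trend adjusted p = 7.97e-04). A frameshift can remove a protein and leave its RNA, so the RNA level does not by itself check the genotype labels. The related thioesterase Lypla1 was 1.37-fold higher in knockout (log2 fold change 0.46 ± 0.054), and Lypla2 was 1.72-fold higher in wild type (log2 fold change -0.78 ± 0.058).

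Knockout cells carried a strong interferon signature. Of 55 tested genes of the type I interferon response list, 54 rose and 1 fell (55 adjusted over the list alone), with a median log2 fold change of 5.72. Ifit1, an interferon-induced protein that binds viral RNA, stood at 0.318 ± 0.142 CPM in wild type and 591 ± 12.7 CPM in knockout (SD, n = 3 each). The 2'-5' oligoadenylate synthetase-like gene Oasl2 went from 1.74 ± 0.162 to 1600 ± 39.8 CPM, and the transcription factor Irf7 from 2.35 ± 0.39 to 677 ± 34.7 CPM. Ifit3 rose 834-fold and Isg15, a ubiquitin-like modifier, 140-fold. Mx1, an antiviral GTPase, had 1 count over the wild-type libraries and 6526 over the knockout libraries, a ratio of 7300 (95% interval 1310 to 288000). The member that fell was Epsti1, named after its value was seen, at a log2 fold change of -2.37. The list was called by camera (adjusted p = 1.05e-18), and with an estimated correlation its adjusted p = 0.0753.

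**Figure D1:**
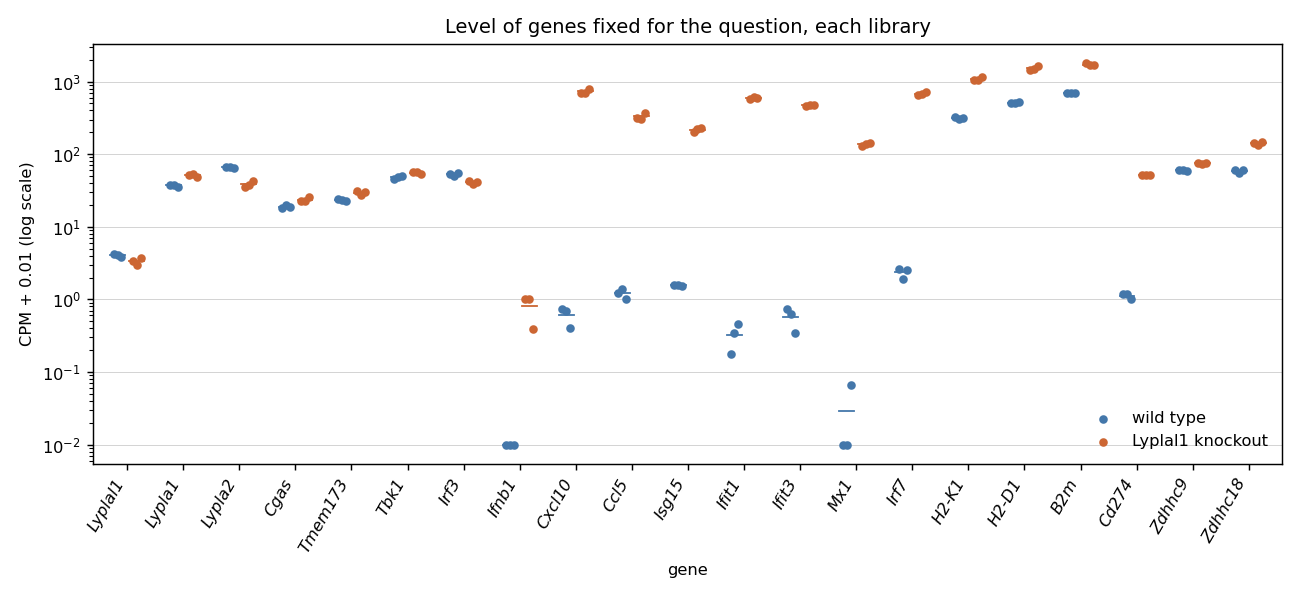
Level of 21 genes fixed for the question (CPM plus 0.01, log scale), with 1 point per library and a line at each group's mean, for wild type (blue, n = 3) and Lyplal1 knockout (orange, n = 3). The interferon-stimulated genes Cxcl10 to Irf7 are far higher in knockout, while Cgas, Tmem173, Tbk1 and Irf3 differ little between the groups.

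The sensor and its adaptor moved little. Cgas (ENSMUSG00000032344, chromosome 9, 78430526 to 78443237) was 1.24-fold higher in knockout, at 19 ± 1.05 CPM in wild type and 23.5 ± 1.63 CPM in knockout (log2 fold change 0.31 ± 0.073, edgeR adjusted p = 3.62e-04). Tmem173, which encodes STING, was 1.26-fold higher and the kinase gene Tbk1 1.16-fold higher. On the deposited TPM these 3 rises were not called (limma-trend adjusted p = 0.175 for Cgas, 0.075 for Tmem173 and 0.915 for Tbk1), and Tbk1 was also not called with upper-quartile factors (edgeR adjusted p = 0.155). The transcription factor gene Irf3 fell, at a log2 fold change of -0.37 ± 0.055, and shares exon sequence with Bcl2l12. Of 30 tested cGAS-STING pathway components 15 rose, 10 fell and 5 were not called (25 adjusted over the list alone). The DNA sensor gene Ifi204 rose 4.11-fold, the ubiquitin ligase gene Trim56 2.04-fold, the transporter gene Abcc1 3.02-fold and the palmitoyltransferase gene Zdhhc18 2.39-fold. The list was not called as a whole (camera adjusted p = 0.375). Ifnb1, the gene of interferon beta, had 0 counts in every wild-type library and 16, 16 and 6 counts in the knockout libraries, at least 14.2-fold higher, and was too low to enter the test.

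RNA of genes for antigen presentation by MHC class I was higher in knockout throughout the list, and presentation itself was not measured. All 26 tested members rose (26 adjusted over the list alone), with a median 4.4-fold change (camera adjusted p = 4.83e-10). With an estimated correlation its adjusted p = 0.0753. The class I heavy chain genes H2-K1 and H2-D1 rose 3.41-fold and 2.99-fold, and B2m, the invariant light chain, rose 2.47-fold to 1710 ± 72.4 CPM. The nonclassical gene H2-T23 rose 10.6-fold, the peptide transporter subunit Tap1 9.5-fold, the peptide loading factor Tapbp 7.04-fold and the transcription factor Irf1 10.2-fold. Heavy chain genes are close in sequence, and how reads shared between them were counted is not stated, so their separate values are less certain than the change of the group.

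Among 22 tested chemokines and inflammatory cytokines 14 rose, 7 fell and 1 was not called (21 adjusted over the list alone). The T cell attractants Cxcl10 and Ccl5 rose 1210-fold and 273-fold, Cxcl10 from 0.597 ± 0.178 to 732 ± 58.6 CPM (SD, n = 3 each). Cxcl16 rose 8.62-fold and the neutrophil attractant Cxcl1 5.05-fold, while Cx3cl1 and Tslp were 5.65-fold and 8.2-fold higher in wild type. The list was not called (camera adjusted p = 0.083), but was called without wild-type replicate 1, 2 or 3 or knockout replicate 3 (camera adjusted p = 0.0359, 0.0395, 0.0299 and 0.0462). It was also called with upper-quartile factors (adjusted p = 0.0351), with no filter (adjusted p = 4.86e-04) and on log2(TPM + 1) (adjusted p = 0.0206). Without the filter low-count members enter, among them Cxcl15, named after its values were seen. This lung marker had 0 counts in each wild-type library and 7, 10 and 49 in knockout replicates 1 to 3. Of 18 tested immune checkpoint and tumour recognition genes 9 rose, 6 fell and 3 were not called (15 adjusted over the list alone, camera adjusted p = 0.34). Cd274, which encodes the checkpoint ligand PD-L1, rose 45.9-fold, Lgals9, galectin 9, 34.8-fold and Cd47 2.12-fold, while Nt5e, an ectonucleotidase that makes adenosine, was 2.34-fold higher in wild type. Of 25 NF-kB target and feedback genes 13 rose, 7 fell and 5 were not called (20 adjusted over the list alone, camera adjusted p = 0.239), with Ptgs2 and Nfkbib 2.54-fold and 4.18-fold higher and Ier3 3.11-fold higher in wild type.

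Ranked by fitted fold change, the 12 genes taken among rises were Rsad2, Iigp1, Olfr56, Mx1, Ifi44, Ly6e, Mx2, Oas2, Trim30a, Ifit1, Cmpk2 and Gbp6. Rsad2 (viperin, chromosome 12, 26442746 to 26456452) went from 7 counts over the wild-type libraries to 72725 over the knockout libraries, and its log2 fold change was 13.42 ± 0.113. Iigp1 and Gbp6, both interferon-inducible GTPases, had no wild-type count and were at least 868-fold and 184-fold higher in knockout. Olfr56 was at least 752-fold higher, but shares exon sequence with the interferon-inducible gene Ifi47, so its reads cannot be told from those of that gene. Oas2 and Cmpk2 had 2 and 3 wild-type counts, and their ratios were 3470 (95% interval 959 to 28600) and 2060 (703 to 9980). A fitted fold is no bound where a group has 0 to 3 counts, so the order and the membership of these rankings are not fixed. The smallest adjusted p among rises belonged to Oasl2, Ifit1 and Xdh, xanthine dehydrogenase, which rose 79.1-fold.

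Ranked the same way, the 12 genes taken among falls were Mboat2, Kctd12b, Bicd1, Msx3, Ly9, Adm, Eomes, Susd1, Tmem98, Esrp1, Rnf152 and Ankrd37. Mboat2, a lysophospholipid acyltransferase gene (chromosome 12, 24830879 to 24964397), had 681 counts over the wild-type libraries and none over the knockout libraries, at least 203-fold lower in knockout. Bicd1, Msx3 and Ly9 were likewise without a knockout count and at least 143-fold, 139-fold and 121-fold lower. Kctd12b had 2110 wild-type counts and 1 knockout count, a ratio of 1890 (95% interval 338 to 74600). The T-box factor gene Eomes had 1329 and 2 counts, a ratio of 594 (164 to 4910), and the vasodilator peptide gene Adm 993 and 1 counts, a ratio of 888 (159 to 35100). Esrp1, a splicing regulator of epithelial cells, was 201-fold higher in wild type. The smallest adjusted p among falls belonged to Car9, Vim and Egln3, at log2 fold changes of -3.98 ± 0.045, -2.41 ± 0.032 and -3.53 ± 0.047.

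Cell cycle transcripts were lower in knockout. Of 40 mitosis and G2/M genes 3 rose, 35 fell and 2 were not called (38 adjusted over the list alone), with a median log2 fold change of -0.63 (camera adjusted p = 2.12e-06, and adjusted p = 0.0753 with an estimated correlation). The spindle motor gene Kif11 was 4.46-fold higher in wild type, the transcription factor gene Foxm1 2.11-fold, the mitotic kinase gene Ttk 2.36-fold and Anln 1.92-fold. Of 40 S phase and DNA replication genes 6 rose, 28 fell and 6 were not called (34 adjusted over the list alone, median -0.40, camera adjusted p = 3.81e-04, and adjusted p = 0.188 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 was 4.03-fold higher in wild type, Uhrf1 2.39-fold, the helicase subunit Mcm7 2.13-fold and the polymerase gene Pole 1.98-fold. Of 29 p53 target and DNA damage response genes 21 rose, 6 fell and 2 were not called (27 adjusted over the list alone, camera adjusted p = 8.62e-03, and adjusted p = 0.218 with an estimated correlation). Trp53 itself rose 2.59-fold, Gadd45a 2.59-fold, Atf3 4.15-fold and Ei24 1.79-fold. The p53 target Cdkn1a, the cell cycle inhibitor p21, named after its value was seen, fell from 343, 340 and 335 counts in wild type to 132, 178 and 146 in knockout.

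Genes of hypoxia and glycolysis were lower in knockout. Of 33 tested, 5 rose, 27 fell and 1 was not called (32 adjusted over the list alone), with a median log2 fold change of -1.02 (camera adjusted p = 2.84e-06, and adjusted p = 0.193 with an estimated correlation). Carbonic anhydrase 9, a classical target of hypoxia-inducible factor, went from 349 ± 4.42 to 22.1 ± 1.21 CPM (SD, n = 3 each). The oxygen sensors Egln3 and Egln1 were 11.5-fold and 4.95-fold higher in wild type, while Pfkfb3, an activator of glycolysis, rose 12.6-fold in knockout. Nuclear genes of oxidative phosphorylation went the other way. Of 49, 43 rose, 3 fell and 3 were not called (47 adjusted over the list alone, median 0.57, camera adjusted p = 2.63e-06, and adjusted p = 0.356 with an estimated correlation). Ndufb9 rose 2.4-fold, Ndufa10 1.97-fold, Sdhb 1.8-fold and Uqcrc2 1.69-fold. The messages encoded in mitochondrial DNA fell in all 7 cases tested (7 adjusted over the list alone, median -2.41, camera adjusted p = 1.90e-04, and adjusted p = 0.23 with an estimated correlation), while the other 6 listed messages had 0 counts in every library. mt-Nd1, mt-Nd2, mt-Nd5 and mt-Co1 were 5.3-fold, 5.29-fold, 8-fold and 3.38-fold higher in wild type, and mt-Nd5 overlaps mt-Nd6. The share of counts from mitochondrially encoded genes was 1.89%, 1.85% and 1.80% in wild type and 0.55%, 0.53% and 0.51% in knockout.

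Stress response genes were higher in knockout. Of 35 genes of the unfolded protein and integrated stress response 30 rose and 5 fell (35 adjusted over the list alone, median 0.73, camera adjusted p = 1.11e-05, and adjusted p = 0.149 with an estimated correlation). The endoplasmic reticulum chaperones Hspa5 and Hyou1 rose 3.57-fold and 3.66-fold, and the stress factors Ddit3 and Ppp1r15a rose 7.58-fold and 7.69-fold. Of 25 NRF2 antioxidant response genes 20 rose, 4 fell and 1 was not called (24 adjusted over the list alone, median 0.83, camera adjusted p = 4.42e-04, and adjusted p = 0.23 with an estimated correlation). The ferritin heavy chain gene Fth1 rose 8.33-fold to 12500 ± 517 CPM, Gsta4 7.48-fold and G6pdx 2.62-fold. Of 15 heat shock protein genes 11 rose, 2 fell and 2 were not called (13 adjusted over the list alone, camera adjusted p = 0.0233, and adjusted p = 0.366 with an estimated correlation), among them Hspd1 at 2.92-fold, Cryab at 3.67-fold, Serpinh1 at 1.66-fold and Hsph1 at 1.62-fold. Of 75 cytosolic ribosomal protein genes 42 rose, 11 fell and 22 were not called (53 adjusted over the list alone, camera adjusted p = 0.0227, and adjusted p = 0.449 with an estimated correlation), and this list was not called with upper-quartile factors (adjusted p = 0.0585) or on TPM (adjusted p = 0.104). Rpl8 rose 1.54-fold, Rpl10a 2.01-fold, Rpl10 1.91-fold and Rpl35a 2.9-fold, but these genes have many pseudogenes that can share their reads.

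**Figure D2:**
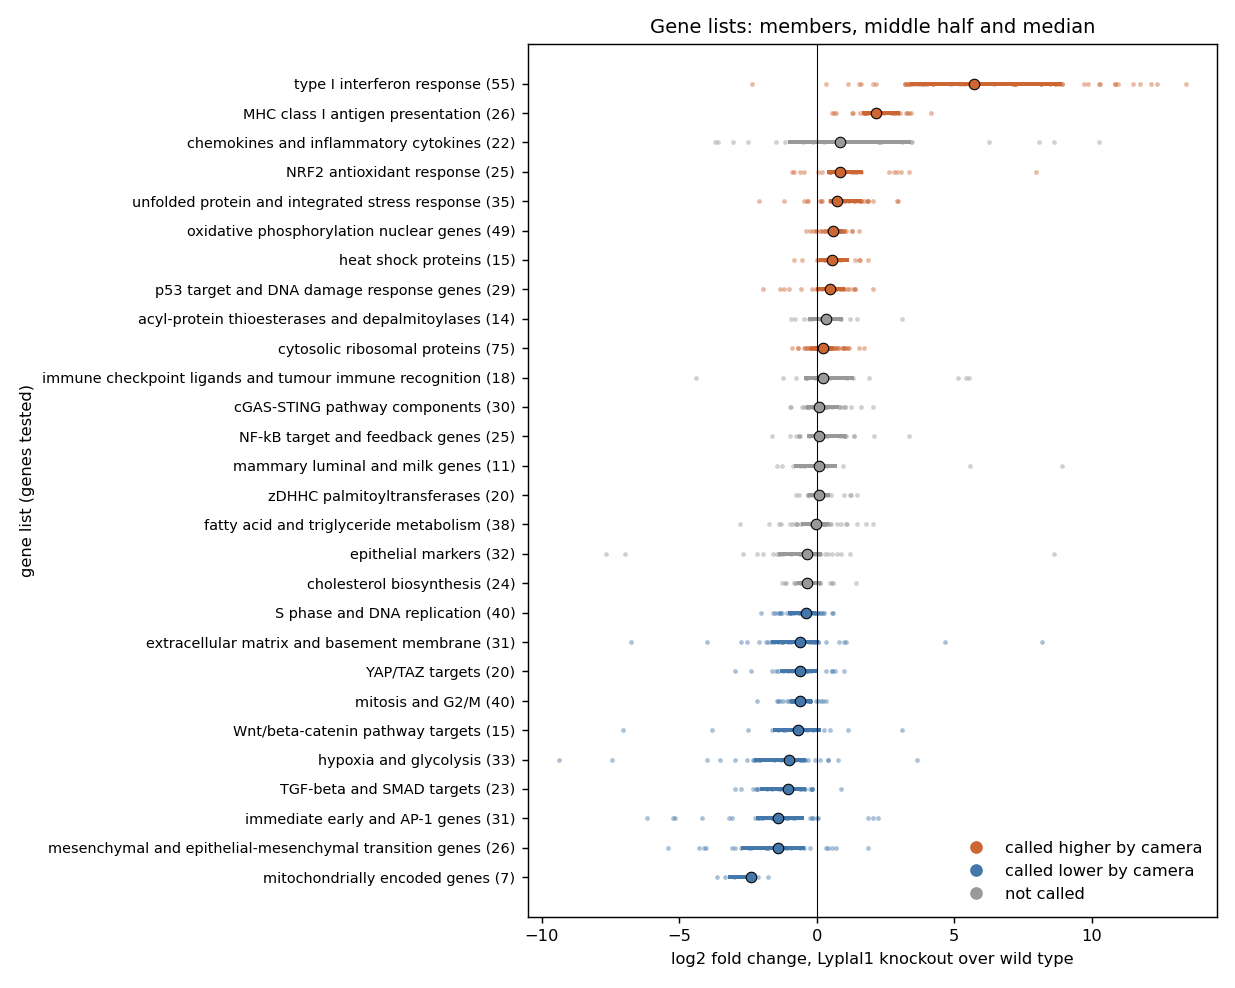
Log2 fold changes (knockout over wild type) of the tested members of 28 gene lists, with small points for genes, a bar for the interquartile range and a large point for the median. The interferon response has the highest median, at 5.72, and mitochondrially encoded genes the lowest, at -2.41; orange and blue mark lists called higher or lower by camera with the preset correlation.

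Most mesenchymal and matrix genes on the lists were lower in knockout. Of 26 mesenchymal and epithelial-mesenchymal transition genes 5 rose, 20 fell and 1 was not called (26 adjusted over the list alone, median -1.41, camera adjusted p = 3.15e-04, and adjusted p = 0.23 with an estimated correlation). The intermediate filament gene Vim went from 3210 ± 40.9 to 606 ± 14.2 CPM (SD, n = 3 each), and Tnc and Ccn2 were 19.5-fold and 7.88-fold higher in wild type. Of 31 extracellular matrix and basement membrane genes 6 rose, 22 fell and 3 were not called (28 adjusted over the list alone, camera adjusted p = 5.29e-03, and adjusted p = 0.218 with an estimated correlation). Lamb1, Col6a1, Fbln2 and Plod2 were 3.63-fold, 6.79-fold, 3.45-fold and 4.32-fold higher in wild type. With no filter on low counts the mean of this list was 0.38, on the other side of 0, and it was not called (adjusted p = 0.089). Of 32 epithelial markers 8 rose, 20 fell and 4 were not called (29 adjusted over the list alone, camera adjusted p = 0.0625), and the list was called without knockout replicate 3 (adjusted p = 0.0462). The keratins Krt19 and Krt18 were 3.87-fold and 2.72-fold higher in wild type, while the tight junction gene Cldn3 had 2 wild-type and 848 knockout counts, a ratio of 474 (95% interval 131 to 3920).

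Of 31 immediate early and AP-1 genes 3 rose, 26 fell and 2 were not called (29 adjusted over the list alone, median -1.40, camera adjusted p = 4.97e-05, and adjusted p = 0.218 with an estimated correlation). Dusp6 and Ier2 were 9.21-fold and 8.46-fold higher in wild type, while Dusp4 rose 3.65-fold. Of 23 TGF-beta and SMAD targets 1 rose, 21 fell and 1 was not called (23 adjusted over the list alone, median -1.06, camera adjusted p = 1.23e-05, and adjusted p = 0.149 with an estimated correlation), with Pmepa1 4.37-fold and Ltbp3 2.57-fold higher in wild type. Of 20 YAP/TAZ targets 5 rose and 15 fell (20 adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.23 with an estimated correlation), with Ankrd1 3.06-fold, Ccn1 2.66-fold and Amotl2 2.82-fold higher in wild type. Of 15 Wnt/beta-catenin pathway targets 4 rose and 11 fell (15 adjusted over the list alone, camera adjusted p = 0.0411, and adjusted p = 0.334 with an estimated correlation), a call lost in 6 alternatives: upper-quartile factors (adjusted p = 0.0697), no filter (0.0890), the replicate block (0.0564), log2(TPM + 1) (0.0805), without wild-type replicate 3 (0.0516), and without genes higher in knockout replicate 3 (0.0613). The receptor Lgr6 was 14-fold, the Wnt inhibitor Sfrp1 132-fold, Tcf7 5.65-fold and Myc 2.36-fold higher in wild type.

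Lipid and palmitoylation genes moved in both directions. Of 24 cholesterol biosynthesis genes 5 rose, 16 fell and 3 were not called (21 adjusted over the list alone, camera adjusted p = 0.0625), and the list was called lower with no filter (adjusted p = 0.0354). Stard4 was 2.22-fold higher in wild type and Ebp rose 2.65-fold. Of 38 fatty acid and triglyceride metabolism genes 17 rose, 18 fell and 3 were not called (35 adjusted over the list alone, camera adjusted p = 0.911). The desaturase genes Scd1 and Scd2 were 6.98-fold and 2.59-fold higher in wild type, while Acadl, of fatty acid oxidation, rose 4.08-fold and the lipid droplet gene Plin2 3.49-fold. Of 14 acyl-protein thioesterases and depalmitoylases 8 rose, 4 fell and 2 were not called (12 adjusted over the list alone, camera adjusted p = 0.34), among them Abhd12 at 2.77-fold, Abhd16a at 2.29-fold and Abhd17c at 1.83-fold higher in knockout, and Pla2g15 at 1.9-fold higher in wild type. Of 20 zDHHC palmitoyltransferase genes 9 rose, 6 fell and 5 were not called (15 adjusted over the list alone, camera adjusted p = 0.47), and the sign of their mean change turned on log2(TPM + 1), to -0.01. Zdhhc9 rose 1.25-fold, Zdhhc4 2.78-fold and Zdhhc8 1.99-fold, and Zdhhc2 was 1.69-fold higher in wild type. Zdhhc9 lies on X, where the median rise was 1.45-fold, and Zdhhc8 on chromosome 16, where the median rise was 1.62-fold. Of 11 mammary luminal and milk genes 5 rose, 5 fell and 1 was not called (10 adjusted over the list alone, camera adjusted p = 0.911), with Ly6a 482-fold and Cited1 47.3-fold higher in knockout and Krt8 1.53-fold higher in wild type.

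Lists of leukocyte and stromal markers had too few tested genes for camera. Of 4 tested macrophage and monocyte markers, Cd68, a lysosomal protein gene, rose 56.9-fold in knockout, Lyz2 was called higher by edgeR and the other 2 were not called (1 adjusted over the list alone). Lyz2 lost its call with limma-voom (adjusted p = 0.0687) and in edgeR with no filter (adjusted p = 0.0941). Its call was also lost without wild-type replicate 1, 2 or 3 or knockout replicate 2. Of 3 lymphocyte markers Cd5 and Trac fell and Lck rose (3 adjusted over the list alone). Of 4 fibroblast markers Pdgfra rose 2.63-fold and Col1a1, Gsn and Loxl1 fell (4 adjusted over the list alone), and of 4 endothelial markers Flt1 and Egfl7 fell (2 adjusted over the list alone). Lung transcripts appeared in the knockout libraries, a set of markers looked at only after the data had been seen. The surfactant gene Sftpc had 1, 0 and 0 counts in wild type and 109, 142 and 691 in knockout replicates 1 to 3. The club cell gene Scgb1a1 had 2, 1 and 2 against 185, 239 and 1085, and Lyz2 had 1, 0 and 0 against 28, 45 and 263. The skeletal muscle gene Acta1, named like Myh8 after its values were seen, had 0, 2 and 2 against 12, 10 and 148. Of 4 tested skeletal muscle markers, also listed after the data had been seen, 0 were called higher and 1 lower. The lower one was Tnni2, with 93, 91 and 83 against 3, 3 and 20.

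**Figure D3:**
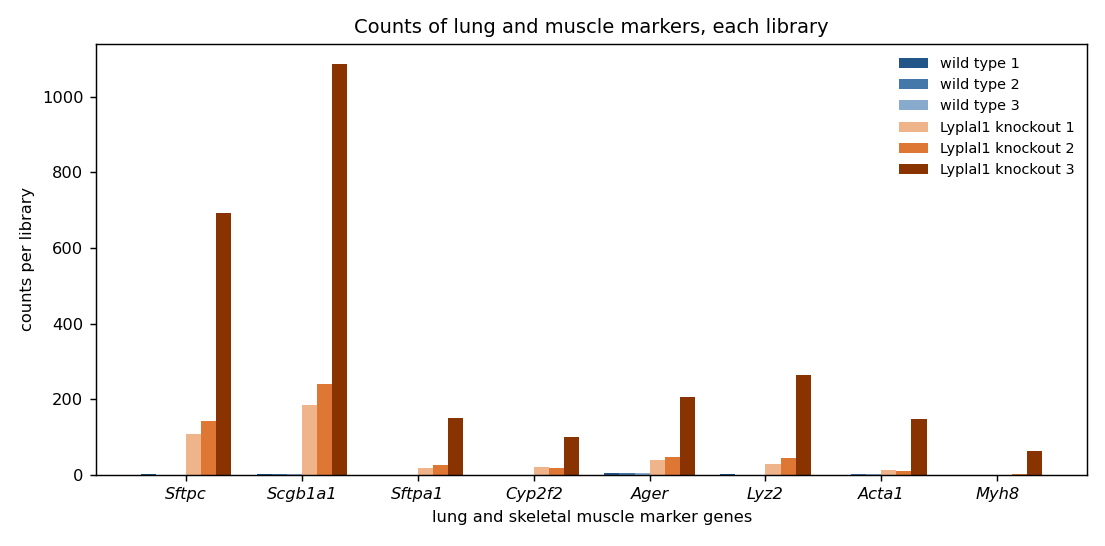
Counts of 6 lung markers and the skeletal muscle markers Acta1 and Myh8 in each library, as bars from 0, with blue for wild type and orange to brown for Lyplal1 knockout. Counts are near 0 in every wild-type library and highest in knockout replicate 3, where Scgb1a1 reached 1085 counts.

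In all, edgeR's quasi-likelihood test called 10711 of 13022 genes (82.3%) at an adjusted p under 0.05, with 5382 higher and 5329 lower in knockout, and 3643 of the called genes changed by at least 1 on the log2 scale. The libraries of the groups did not overlap for 10821 genes (83.1%), where chance gives 10%. The split depended on the scaling: the higher genes were 50.2% of calls with TMM factors, 42.8% with upper-quartile factors and 38.5% on log2(TPM + 1). Upper-quartile factors moved the median of all genes by -0.13 and log2(TPM + 1) by -0.20 on the log2 scale, so changes of that size are not fixed in direction by these data. Camera called 18 of 28 lists with the preset correlation, 8 higher and 10 lower, and 0 with a correlation estimated per list.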

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

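The count of called genes stayed within 1.5 times of 10711 under every alternative run, from 8369 in the test against a 1.2-fold change to 12030 with no filter, and leaving out each library gave 10504 to 10776. Counts of genes changed by at least 2-fold ran from 2955 on log2(TPM + 1) to 5165 with no filter. Of genes changed in Lyplal1 knockout, 10541 were called without genes at least 2-fold higher in knockout replicate 3 than in the others, an alternative chosen after seeing the data.

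With the replicate number as a block, 10798 genes were called. Same-numbered libraries of the groups had correlations of their deviations of -0.007, 0.042 and 0.013, which gives no sign of pairing. Under the block only the Wnt/beta-catenin list lost its call (adjusted p = 0.0564), and no other described list and no named gene did.

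The Lyplal1 change was called with upper-quartile factors (-0.41), on log2(TPM + 1) (-0.44) and on log2(TPM + 0.1) (-0.48), scales on which the median of all genes also moved, by -0.133, -0.204 and -0.207. It was not called elsewhere, and leaving out each library gave -0.34 to -0.20. With an estimated correlation camera lost the interferon list (mean log2 fold change 6.25) and the MHC class I list (2.23). The mitosis and G2/M list lost its call too, though its estimated correlation of 0.009 was below the preset 0.01. A higher correlation between genes therefore cannot account for that loss, and the cause was not tested further. A call lost with an estimated correlation is thus not by itself a sign that the genes of a list are correlated. Fry, which does not compare a list with other genes, called 27 of 28 lists, the cGAS-STING list among them (mean 0.22, adjusted p = 4.51e-06).

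These mean changes turned sign, none of them past the threshold afterwards, and the cause was not tested: the zDHHC list on log2(TPM + 1) (-0.014), and the extracellular matrix list (0.38) and the fatty acid list (0.17) with no filter. Of 183 named genes with a fit, 173 kept their call under every alternative run and 10 lost it under some, with 0 reversals. These were Cgas, Tmem173 and Tbk1 under other scalings, and 7 genes of the lung lists. At this depth, genes with 0 to 3 counts over a group have folds set by the floor or a wide interval.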

Other observations

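Some gene families were gathered into lists only after the data had been seen, so their counts describe genes chosen for the pattern and test nothing further. All 18 interferon-inducible GTPase genes of the GBP and IRG families rose, with a median log2 fold change of 8.31, or 7.18 with genes lacking a wild-type count held at their bound, and Gbp2, Gbp3 and Gbp7 are also in the type I interferon list. Of 11 inflammasome and pyroptosis genes 8 rose and 3 fell. Zbp1, a sensor of Z-form nucleic acid that is also in the type I interferon list, had 8, 5 and 8 counts in wild type and 2837, 2866 and 2863 in knockout, and Casp1 had 0 in each against 137, 135 and 137. In the MHC class II list Cd74 and H2-Oa rose and 1 gene was not called.

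Some genes were near silent in the libraries of one group and well detected in those of the other. A mean of at least 10 CPM in knockout with under 0.1 CPM in wild type was seen for 24 genes, and the reverse for 6. Of the 24, 5 are in the type I interferon list, 4 in the GBP and IRG list and 3 (Scgb1a1, Sftpb and Sftpc) in the lung lists, with no test of enrichment. Outside these lists Hexa, a lysosomal enzyme gene, had 1 count over the wild-type libraries and 1048 over the knockout libraries, Ubqln2 had 5 and 3377, and Parvb 3 and 1807. Hexa, Ubqln2 and Parvb were chosen after their values were seen.

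The tests of lung RNA and of the nuclear respiratory chain genes were chosen only after the results were seen, and the lists of lung markers, histone genes and mitochondrial DNA maintenance genes were written after the data had been seen. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many called genes, 10711 against at most 0 in the others, and 10 splits are too few for a share under 0.05. Every other split mixes the groups on each side. With groups this far apart, few calls were likely from them beforehand, so the contrast adds no support.

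Changes gathered by chromosome: on chromosome 16, 73% of 393 tested genes rose (odds ratio 4.0, Fisher's exact test, two-sided, adjusted p = 2.02e-36), with a median log2 fold change of 0.70, while X and chromosome 1 lay at 0.53 and 0.31 and chromosomes 12 and 8 at -0.32 and -0.30. On log2(TPM + 1), where the median over all genes lay lower, these medians were 0.45 for chromosome 16, 0.31 for X, 0.09 for 1, -0.47 for 12 and -0.48 for 8. The chromosome 16 median stayed at 0.66 without immune list members and genes at an absolute log2 fold change of 2 or more, and at 0.73 after trends on GC content and exon length were removed, which argues against interferon genes on it and those biases as the cause. A copy number difference between the cell populations may account for such shifts. Some genes named above lie in shifted regions. Zdhhc9 (0.327) is on X, and Zdhhc8, Cd47 and Abcc1 (0.995, 1.081 and 1.595) are on chromosome 16. Rpl8 (0.619) lies in a stretch of 50 genes on chromosome 15 with a median of 1.074. Their changes were not set apart from these shifts. After the running median of 50 neighbours was subtracted, 83.3% of the 3620 placed genes called at 2-fold or more kept that size. Medians of such windows ran only from -0.686 to 1.074, so broad shifts do not account for most large changes. Windows of this size miss gains or losses of a few genes, so smaller copy number changes stay untested. Whether the knockout or a separate history of the populations lies behind the remainder stays open and untested, as a single knockout population does not separate them.

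Lung transcripts in the knockout libraries varied together. Over 33 markers the ratio of knockout replicate 3 to the mean of replicates 1 and 2 had a median of 5.16 (interquartile range 3.27 to 6.78), as RNA from lung tissue in these libraries would give. Sftpb was less skewed, at 1.62, and the lung lists hold genes such as Abca3, Cbr2 and Rtkn2 that wild-type cells also express. For the 54 risen interferon genes the same ratio was 1.01 (interquartile range 0.97 to 1.06), so that RNA is not a likely source of the interferon signature. No biological explanation of the lung transcripts was tested.

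Mitochondrially encoded messages fell while nuclear genes of oxidative phosphorylation had a median of 0.57. The joint fall predicted for fewer mitochondria with all their components was therefore not seen. RNA levels do not measure the number of mitochondria, so they do not exclude it. Genes of mitochondrial DNA maintenance and transcription went both ways (9 higher, 6 lower and 7 not called, median 0.12), so their part stays open. Top1mt, Pnpt1 and Lrpprc stood at 1.60, 1.55 and 0.94 and the helicase gene Twnk at -0.75, all chosen after their values were seen. Replication-dependent histone genes, whose RNA typically lacks poly(A), had a median of -1.70 over the 8 tested of 62 listed (1 higher, 6 lower, camera adjusted p = 0.229, and adjusted p = 0.46 with an estimated correlation). Whether the RNA counted for these 8 lacked poly(A) is not known, so they are a weak gauge of capture. A library preparation that captured RNA without poly(A) differently could also give their fall, though S phase genes fell too. Whether mitochondrially encoded messages would follow such a difference in capture was not tested. Small nucleolar RNAs, also without poly(A), had summed counts of 523, 523 and 527 in wild type and 511, 534 and 500 in knockout. Sums this low, in libraries of 16731209 to 17108975 counts, leave little such RNA to compare and do not decide whether capture differed. In the other direction, mt-Rnr1, the 12S ribosomal RNA, rose by 1.75 (mt-Rnr1 and mt-Rnr2 were chosen after their values were seen). The 10 tested mitochondrial transfer RNAs fell and mt-Rnr2 changed by -0.40, and both the preparation and an effect of the knockout stay open.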
